A study of Mus musculus with 12 samples.

How the data were processed

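The series holds 12 samples of mouse embryonic stem (ES) cells: 9 RNA samples and 3 samples for genome-wide methylation sequencing. The 6 RNA libraries of wild-type and Drosha-deficient cells were analysed, 1 library per genotype in each of 3 RNA fractions. The 3 RNA samples of Dnmt1-deficient cells and the 3 methylation samples were not analysed here. Per the labels' protocols, cells were grown in serum medium with leukemia inhibitory factor, RNA was extracted with Trizol, long and short RNA were separated on a small RNA isolation kit, and mRNA was selected with an oligo-dT kit. The same labels say that RNA libraries were made with a small RNA library kit. Whether the counting of reads used the strand is not given in the sources used here. Samples were grouped by genotype and fraction from their titles. The labels name no sample of long RNA; the table of long RNA was assigned to the samples titled total RNA because the mRNA and short RNA tables match the other titles, and this assignment rests on elimination.

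The authors deposited 3 tables of gene-level values in FPKM (fragments scaled to transcript length and library size), with wild type as the first and Drosha-deficient as the second value, per the file headers. Each table has 36883 rows with the same identifiers in the 3 tables. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.0.10, Cufflinks 2.1.1 and Cuffdiff were used, with the mouse genome build mm10/GRCm38; the annotation and the way library sizes were scaled are not given in the sources used here. The authors' log2 fold change in each deposited table equals the log2 ratio of both FPKM values within 0.001, except in 8 mRNA and 42 long RNA rows that the authors' status column marks as failed or too deep. The authors' p-value and q-value of each deposited table come from Cuffdiff and rest on 1 library per genotype, so they compare these libraries and not the genotypes. In mRNA 16918 rows had the status OK, in long RNA 16160 and in short RNA 2597. Gene names came from the tables themselves; of 36122 distinct single names, 27266 (75.5%) were symbols of the RefSeq gene table for GRCm38, which gave each gene's class and the genes lying inside another. In 429 rows the long RNA table gives another gene name than the mRNA table, and each table's own names were used for the lists.

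FPKM values are not counts, so no count model was used. For each row the log2 difference was log2((Drosha-deficient FPKM + 1)/(wild-type FPKM + 1)), with a pseudocount of 1. This scale understates the differences of genes of low level. Rows entered a comparison when the authors' status was OK and at least 1 of both libraries reached 1 FPKM. Such a row was called higher or lower in Drosha-deficient cells when its log2 difference was at least 1 in size, which is 2-fold. With 1 library per genotype and fraction there is no replicate check, no p-value and no batch that could be fitted. Levels were not compared across the 3 tables, which were normalized separately; only differences within a table were. For mRNA and long RNA together, genes called the same way in both were counted beside the overlap that independent lists of these sizes would give. Pearson's r and Spearman's rho were computed across genes, which are not independent replicates.

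For each of 30 gene lists, 21 for mRNA and long RNA and 9 for short RNA, the members called higher, lower or neither were counted. The median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. The lists covered the microRNA pathway, DNA methylation, pluripotency, neural and epiblast, mesoderm, endoderm, trophoblast and fibroblast markers, imprinted genes, germline genes silenced by promoter methylation, the reproductive homeobox cluster, the 2-cell-like state, reported targets of miR-290 with miR-302 and of let-7, transcripts that carry microRNA hairpins, replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, the cell cycle, p53 targets and the interferon response. For short RNA they covered all microRNA genes, the miR-290, miR-302, miR-17 and let-7 groups, the Dlk1-Dio3 microRNAs, microRNAs that do not need Drosha, small nucleolar RNAs and other structural RNAs. The named genes followed a rule: Drosha, Dgcr8, Dicer1 and a set of methylation and pluripotency genes; the 12 highest and the 12 lowest genes in both mRNA and long RNA by the smaller of both differences; the 10 highest and 10 lowest rows of short RNA and its 10 microRNA genes with the highest wild-type level; up to 2 higher and 2 lower members of each list; and the 6 genes with the largest difference between fractions in each direction. Rows with several gene names were counted and not named. The groups, lists, naming rule and the alternatives not marked as added were fixed before the data were examined. Lists of chaperones, keratins and the expected direction of imprinted genes, and the grouping by RefSeq class, were added after the data had been seen.

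The tables give no counts, and depth was estimated from the steps of low values, since 1 fragment on a gene of fixed length has a fixed FPKM. Low rows gave a depth of the Drosha-deficient over the wild-type library of 1.14 in mRNA, 1.20 in long RNA and 1.17 in short RNA. Values of single fragments on pseudogenes of known length gave about 22200000 and 25200000 fragments for the wild-type and Drosha-deficient mRNA libraries, 18900000 and 22600000 for long RNA, and 2690000 and 3070000 for short RNA. These are effective depths after the authors' scaling, and estimates. Rows of microRNA length in mRNA and long RNA rest on few fragments, and values of multicopy genes, pseudogenes and overlapping genes depend on how shared reads were divided.

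The alternatives were a pseudocount of 0.1 or 5, no minimum FPKM or a minimum of 5, log2 differences centred on their median, all rows except failed ones, rows of the same symbol summed, and a stricter q-value of 0.01 for the authors' calls. Counts over protein-coding genes alone, the 2-cell-like list cut to a few members taken as outside multicopy families, and random lists matched on gene span were added after the data had been seen. The steps were tested on simulated libraries with 200 genes of known fold, in which fragments were drawn from the wild-type levels. These genes were taken only from rows above the minimum FPKM in wild type. The shares of them that were called do not cover the lowest rows. Over 14225 simulated mRNA rows, 100% of the 50 genes set 3-fold apart were called in the right direction and 0.121% of unchanged rows were called; over 13501 long RNA rows these shares were 90.0% and 0.293%, and over 2506 short RNA rows 76.0% and 1.95%. Of 100 random lists in each simulated table, 6% in mRNA, 4% in long RNA and 6% in short RNA lay outside the percentile bounds of 2.5 and 97.5. Simulated depth ratios of 1.15, 1.20 and 1.17 were recovered as 1.15, 1.20 and 1.17. The simulation holds sampling noise only, and no variation between cultures or library preparations. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.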

Results

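RNA was compared between wild-type mouse ES cells, which are cultured cells of the early embryo that can form all its tissues, and ES cells deficient in Drosha, the nuclear ribonuclease that cuts hairpins out of primary microRNA transcripts. The series title concerns a role of Drosha in keeping CG methylation, and the RNA tables give the expression side of that question. For each genotype 1 library was made from each of 3 fractions: mRNA selected by its poly(A) tail, long RNA and short RNA. No library had a replicate, so no difference reported here has a replicate check. Values are FPKM as deposited, and higher or lower means at least 2-fold between both libraries of a fraction on the log2(FPKM + 1) scale. Fold values given for single genes are ratios of FPKM without the pseudocount. By estimate, the mRNA libraries held about 22200000 (wild type) and 25200000 (Drosha-deficient) fragments, the long RNA libraries 18900000 and 22600000, and the short RNA libraries 2690000 and 3070000. Hence 1 fragment on a transcript of 1 kb stood for 0.0450 and 0.0398 FPKM in mRNA, 0.0530 and 0.0443 FPKM in long RNA, and 0.371 and 0.326 FPKM in short RNA, so low values are least precise in short RNA.

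Drosha (chromosome 15, 12824815 to 12935290, mm10/GRCm38, protein-coding) stood at 42.1 FPKM in the wild-type and 6.22 FPKM in the Drosha-deficient mRNA library, 6.77-fold lower. In long RNA it stood at 21.2 and 4.34 FPKM, 4.87-fold lower, so the direction matched the genotype labels in both fractions. The short RNA row of Drosha had 2.26 and 0.973 FPKM and did not pass the filter. Dgcr8 (chromosome 16, 18239784 to 18289249), the partner of Drosha whose own mRNA carries hairpins that Drosha cuts, was 5.92-fold higher in mRNA, from 12.4 to 73.5 FPKM, and 5.57-fold higher in long RNA. Dicer1, which cuts the hairpins that Drosha releases, had 16.6 and 26.0 FPKM in mRNA and 18.2 and 20.8 FPKM in long RNA and was called in neither. Of 25 measured genes of the microRNA pathway in mRNA, 4 were higher and 1 was lower, with a median log2 difference of 0.38 (percentile 99.2). In long RNA 2 of 24 were higher and 1 was lower, with a median of 0.11 (percentile 86.9). Tnrc6a, a scaffold of the silencing complex, was among the higher genes in both, at 9.09 and 21.3 FPKM in long RNA. Which part of the Drosha locus was disrupted is not given in the sources used here, so the remaining signal does not measure intact transcript.

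Short RNA addressed which small RNAs were lower without Drosha. The microRNA genes were lower almost throughout: of 159 measured, 148 were lower, 6 higher and 5 neither, with a median log2 difference of -5.68 (percentile 0). Mir293, a member of the miR-290 cluster that dominates mouse ES cells, had the highest wild-type level and went from 1136290 to 350 FPKM (chromosome 7, 3220343 to 3220422). All 7 measured genes of that cluster were lower, among them Mir292, from 556982 to 17368 FPKM, and Mir294, from 45569 to 601 FPKM. All 5 measured genes of the miR-302 cluster and all 5 of the miR-17 to 92 family were lower as well. So were all 4 of the let-7 family and all 26 of the Dlk1-Dio3 region on chromosome 12. The medians of these groups, in this order, were -6.45, -11.85, -6.41 and -9.50, and that of the miR-290 cluster was -5.003. In the miR-17 to 92 family, Mir92-2, Mir363 and Mir18b lie on chromosome X, apart from the miR-17 to 92 cluster of Mir17hg on chromosome 14. Other abundant microRNAs included Mir183 (243378 and 2423 FPKM), Mir148a (190794 and 95.5 FPKM), Mir7-2 (181082 and 5126 FPKM), Mir295 (115394 and 1721 FPKM), Mir379 (91381 and 35.0 FPKM), Mir291a (83824 and 3027 FPKM) and Mir127 (74500 and 796 FPKM).

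The 10 lowest rows of short RNA were all microRNAs listed at 0 in Drosha-deficient cells: Mir99b, Mir434, Mir92-2, Mir363, Mir181d, Mir27a, Mir337, Mir376b, Mir23a and Mir18b. Their wild-type levels ran from 3693 FPKM for Mir18b to 22993 FPKM for Mir99b. For the microRNA groups, the matched random lists at these levels hold mostly other microRNAs. The percentiles compare each group mostly with them (8.63 for miR-290, 2.04 for miR-302, 0.03 for the miR-17 to 92 family, 0 for let-7 and for Dlk1-Dio3).

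**Figure D1:**
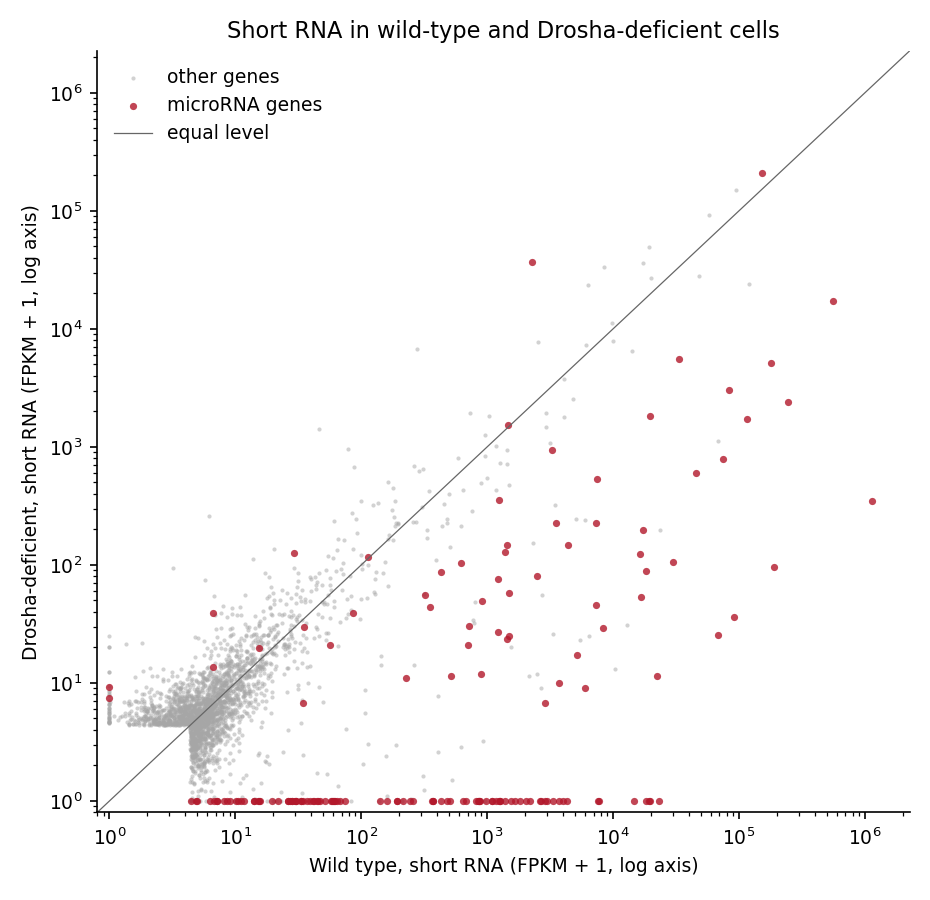
Level of each gene that passed the filter in short RNA, in FPKM + 1 on log axes, in the wild-type library (horizontal) and the Drosha-deficient library (vertical), 1 library each; red points are microRNA genes, grey points other genes, and the line marks equal levels. Of the 159 microRNA genes, 148 lie at least 2-fold below the line, many of them at 0 FPKM in Drosha-deficient cells.

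Among microRNAs listed beforehand as made without Drosha, 3 were measured and each behaved differently. Mir320, whose hairpin is a transcript of its own, was 16.2-fold higher, from 2270 to 36857 FPKM. Mir5099 was called neither higher nor lower, at 151520 and 207566 FPKM, although its rows were lower in mRNA (3371 and 470 FPKM) and long RNA (32010 and 3014 FPKM), and Mir484 went from 373 FPKM to a value listed at 0. Structural small RNAs were mostly higher: 5 of 7 measured, with 1 lower and a median log2 difference of 1.41. Terc, the RNA of telomerase, had 78.2 and 952 FPKM, and Rn7sk, which holds a transcription elongation factor inactive, had 8450 and 33603 FPKM, while Rny1, a Y RNA, was lower at 121237 and 24165 FPKM. The highest rows of short RNA were Gm26035, Gm24105, Hist2h2aa1 (a histone H2A gene), Gm6654, Gm26191, Gm26339, Gm10180, Mir320, Glce and RP23-8J15.1. Gm26191, the most abundant of these after Mir320, had 274 and 6748 FPKM. None of the 7 rows named as small nucleolar RNAs passed the filter, so the planned comparison of microRNAs with small nucleolar RNAs gave no value and the planned reference for short RNA is missing. The 1796 protein-coding rows of short RNA had a median log2 difference of -0.03 (193 higher, 229 lower). In long RNA the log2 difference was 0.12 for Rn7sk, 0.25 for Terc and -0.52 for Rny1. Rmrp and Rpph1, at 1.61 and 1.41 in short RNA, were at -0.58 and -1.88 in long RNA. Across all 2597 measured rows, 384 were higher and 477 lower, with a median of -0.03. With all rows except failed ones the counts were 822 and 883, and with a pseudocount of 5 they were 131 and 279. Among protein-coding rows, several of the lowest in short RNA hold annotated microRNA genes, and their values are those of the whole row.

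The next comparison asked which genes differed in both mRNA and long RNA. Genes of the 2-cell-like state, a rare state of ES cell cultures that expresses genes of the cleavage embryo, were higher together. In mRNA 18 of 20 measured members were higher and none was lower, with a median log2 difference of 1.89 (percentile 100), and in long RNA 19 of 21 were higher, with a median of 2.05 (percentile 100). Zscan4f, a telomere-associated gene of that state, had 3.61 and 27.8 FPKM in mRNA and 2.25 and 37.8 FPKM in long RNA, and Usp17lb, a deubiquitinase gene, had 0.613 and 9.01 FPKM in mRNA. Many of these genes belong to near-identical families that share reads, so the values of single members are uncertain. After the data had been seen, Sp110, Tmem92, Arg2, Zfp809, Zfp352 and D5Ertd577e alone were kept as genes outside these families. The medians of those measured were 1.40 in mRNA and 1.64 in long RNA. Read sharing of these genes was not checked, and they do not stand for the whole list. Over the whole list the medians were 0.91 and 0.79 with a pseudocount of 5, and 2.83 and 3.42 with one of 0.1.

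Neural and epiblast markers were higher too, 10 of 14 in mRNA and 3 of 13 in long RNA, with medians of 1.17 and 0.84 (percentile 100 in both). Otx2, a homeobox factor of the epiblast and forebrain, was 5.45-fold higher in mRNA (12.4 and 67.3 FPKM) and 5.04-fold higher in long RNA, and Zic2, a zinc finger factor of the neural plate, was 6.78-fold higher in mRNA (4.76 and 32.3 FPKM). Pluripotency genes had medians of 0.50 in mRNA and 0.41 in long RNA (percentile 100 in both); 13 of 36 were higher in mRNA and 9 of 34 in long RNA, and 1 was lower in each. The higher ones included Otx2, which is on both lists, and Dppa2 (12.7 and 43.1 FPKM in mRNA), and the lower one was Socs3, a feedback inhibitor of the leukemia inhibitory factor pathway (22.8 and 9.07 FPKM in mRNA). The core factors were called in neither fraction: in mRNA Pou5f1 had 562 and 700 FPKM, Sox2 257 and 299.8 FPKM, and Nanog 192 and 207 FPKM. Reported targets of the miR-290 and miR-302 families had medians of 0.51 and 0.41 (percentile 100 in both), with 4 of 26 higher in mRNA and 3 of 25 higher and 1 lower in long RNA. Lefty1 and Lefty2, secreted inhibitors of Nodal, were the named ones, at 111 and 311 FPKM and at 43.5 and 125 FPKM in mRNA. Both are also on the pluripotency list, so the medians of these lists are not independent. In mRNA 22 of the 26 targets were called neither higher nor lower, among them Cdkn1a (56.0 and 49.6 FPKM). With a pseudocount of 5 the medians of the neural and epiblast list were 0.67 in mRNA and 0.41 in long RNA, and that of the microRNA targets in long RNA was 0.20.

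Genes that write, read and erase DNA methylation were slightly higher as a list. In mRNA 7 of 36 were higher and 2 lower, with a median log2 difference of 0.33 (percentile 99.5), and in long RNA 4 of 35 were higher and 1 lower, with a median of 0.20 (percentile 99.2). Against random lists matched on gene span, a check chosen after seeing the data, the percentiles were 99.6 and 99.2. Dnmt1, the maintenance methyltransferase (chromosome 9, 20907206 to 20959888), was called in neither fraction: it had 55.9 and 79.6 FPKM in mRNA and 49.5 and 56.4 FPKM in long RNA. The de novo methyltransferases Dnmt3a (31.1 and 70.6 FPKM) and Dnmt3b (39.0 and 94.8 FPKM) were higher in mRNA, with log2 differences of 1.16 and 1.26, and not by the size rule in long RNA, with 0.53 and 0.86. Dnmt3l, their cofactor, had 107 and 82.7 FPKM in mRNA, and Uhrf1, which brings Dnmt1 to replicated DNA, had 105 and 101 FPKM; neither was called in either fraction. Tet1 (28.5 and 45.9 FPKM) and Tet2 (8.26 and 13.6 FPKM), which oxidize methylcytosine, were not called in mRNA. Mat2a, which makes the methyl donor S-adenosylmethionine, was 2.44-fold higher in mRNA (45.8 and 112 FPKM) and higher in long RNA, as was Zbtb38, a reader of methylated DNA. Gadd45a, a stress gene linked to demethylation, was lower in both (46.9 and 19.2 FPKM in mRNA). On the same list Gadd45b was lower in mRNA (24.3 and 10.2 FPKM), while Gadd45g was higher in both fractions (16.6 and 34.4 FPKM in mRNA).

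Fibroblast markers were lower: 8 of 17 in mRNA and 10 of 16 in long RNA, none higher, with medians of -0.96 and -1.07 (percentile 0 in both). Col1a2, a chain of type I collagen, went from 19.6 to 0.116 FPKM in mRNA and from 12.9 to 0.0162 FPKM in long RNA, and Acta2, smooth muscle actin, from 28.4 to 1.41 FPKM in mRNA. The labels mention no feeder layer. Several markers of early lineages outside the neural one were lower too. Of trophoblast markers 6 of 13 were lower in mRNA and 4 of 8 in long RNA (medians -0.86 and -0.83, percentiles 0.10 and 0.08). Among them were the keratins Krt18 (118 and 23.6 FPKM in mRNA) and Krt8 (27.9 and 7.92 FPKM). Krt7, also on the trophoblast list, was lower in both fractions as well. Keratins of simple epithelia thus make up most of the lower trophoblast markers in long RNA. Hand1, lower in mRNA, is on both the trophoblast and the mesoderm list, so these lists are not independent. Of mesoderm markers 4 of 9 were lower in mRNA and 2 of 3 in long RNA (medians -0.83 and -1.08, percentiles 0.78 and 1.71), among them T, the brachyury factor (4.33 and 0.0387 FPKM in mRNA), and Wnt3. Of endoderm markers 5 of 14 and 3 of 9 were lower (medians -0.41 in both, percentiles 5.64 and 4.46, and 1.79 and 2.12 against random lists of like span), among them Krt19 and the basement membrane collagen Col4a2 (6.60 and 2.19 FPKM in mRNA). No marker on these 4 lists was higher in either fraction. With a pseudocount of 5 the medians in mRNA and long RNA were -0.59 and -0.34 for fibroblast, -0.34 and -0.26 for trophoblast and -0.32 and -0.39 for mesoderm markers, and -0.13 in mRNA for endoderm markers. With a minimum of 5 FPKM they were larger in size, at -2.12 and -3.47 for fibroblast and -1.66 and -1.99 for trophoblast markers, and with no minimum they were -0.45 for trophoblast and -0.40 for mesoderm markers in mRNA. Interferon response genes had medians of -0.66 in mRNA (percentile 0.37, 5 of 17 lower) and -0.34 in long RNA (percentile 11.1, 4 of 15 lower); with a pseudocount of 5 the medians were -0.28 and -0.11, and with one of 0.1, -0.70 in long RNA. Bst2, a tether of budding virus, had 191 and 45.5 FPKM in mRNA, and Isg15, a ubiquitin-like modifier, 7.11 and 0.278 FPKM.

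Imprinted genes went both ways, with medians of -0.03 in mRNA and -0.12 in long RNA (percentiles 32.2 and 18.9; with a minimum of 5 FPKM, 0.13 and 0.0013); 3 were higher and 6 lower in each, of 39 and 40 measured. Igf2, a fetal growth factor (chromosome 7, 142650766 to 142670356), was 56.5-fold lower in mRNA (60.9 and 1.08 FPKM) and 73.1-fold lower in long RNA (15.6 and 0.214 FPKM). With the pseudocount its log2 differences were -4.90 in mRNA and -3.78 in long RNA. Grb10, an adaptor that restrains growth signalling, was lower in both (22.1 and 7.21 FPKM in mRNA). Nespas, the antisense transcript of the Gnas locus, and Mirg, a long RNA of the Dlk1-Dio3 region that carries microRNAs, were higher in both, at 0.721 and 6.41 FPKM and at 25.6 and 89.1 FPKM in mRNA. Germline genes silenced by promoter methylation lay near 0, with medians of -0.07 and 0.01 (percentiles 36.2 and 65.3). With a minimum of 5 FPKM these medians were 0.17 and 0.41. In mRNA 2 of 28 were higher and 2 lower, and in long RNA 2 of 24 were higher. There Rpl10l, a ribosomal protein gene of the testis, had 10.1 and 54.8 FPKM and D1Pas1, a helicase gene, 1.98 and 5.31 FPKM. On the same list Ddx4 (7.98 and 7.91 FPKM in mRNA) and Dazl (4.42 and 4.17 FPKM) were called in neither fraction. In the reproductive homeobox cluster Rhox5 was lower in both fractions (54.9 and 6.49 FPKM in mRNA); the list had medians of -0.46 over 6 and -0.20 over 4 measured genes (percentiles 14.9 and 35.2).

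Transcripts that carry microRNA hairpins had medians of 0.33 in mRNA (percentile 98.4) and 0.27 in long RNA (percentile 99.7), with 5 of 25 higher and 2 lower in mRNA and 4 of 26 higher and 1 lower in long RNA. Mir17hg, the primary transcript of the miR-17 to 92 cluster (chromosome 14, 115042879 to 115046727), was 7.66-fold higher in mRNA, from 9.09 to 69.7 FPKM, and 3.55-fold higher in long RNA, while its row in short RNA went from 3739 to 8.98 FPKM. Copz2, a coat protein gene that holds a microRNA, was lower in both (20.1 and 8.14 FPKM in mRNA). Reported let-7 targets, the cell cycle and p53 targets lay near 0, with medians of 0.00, 0.04 and 0.05 in mRNA (percentiles 41.1, 52.6 and 56.7) and -0.14, -0.11 and -0.03 in long RNA (percentiles 14.9, 19.3 and 48.6). In mRNA 5 of 24 let-7 targets, 2 of 37 cell cycle genes and 1 of 24 p53 targets were higher, and 1, 1 and 0 were lower. In long RNA 1 gene of each list was higher and 1 was lower, of 24, 36 and 24 measured. Mycn, a Myc family factor, and Ccne2, a cyclin of the start of S phase, were the named higher genes (51.5 and 113 FPKM, and 6.15 and 15.7 FPKM in mRNA); Dusp9, a phosphatase of the ERK pathway, and Cdkn1c, a cyclin-dependent kinase inhibitor, were the lower ones (41.4 and 16.8 FPKM, and 15.7 and 5.61 FPKM in mRNA). Ribosomal protein genes had medians of -0.13 and -0.28 (percentiles 1.66 and 0.02, and 41.6 in mRNA against random lists of like span); 14 of 79 were higher and 10 lower in mRNA, and 9 of 78 were higher and 11 lower in long RNA. Rps3a2 and Rpl10l were higher and Rpl10a (684 and 179 FPKM in mRNA) and Rps16 (732 and 226 FPKM) lower, and these genes share reads with many processed copies.

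**Figure D2:**
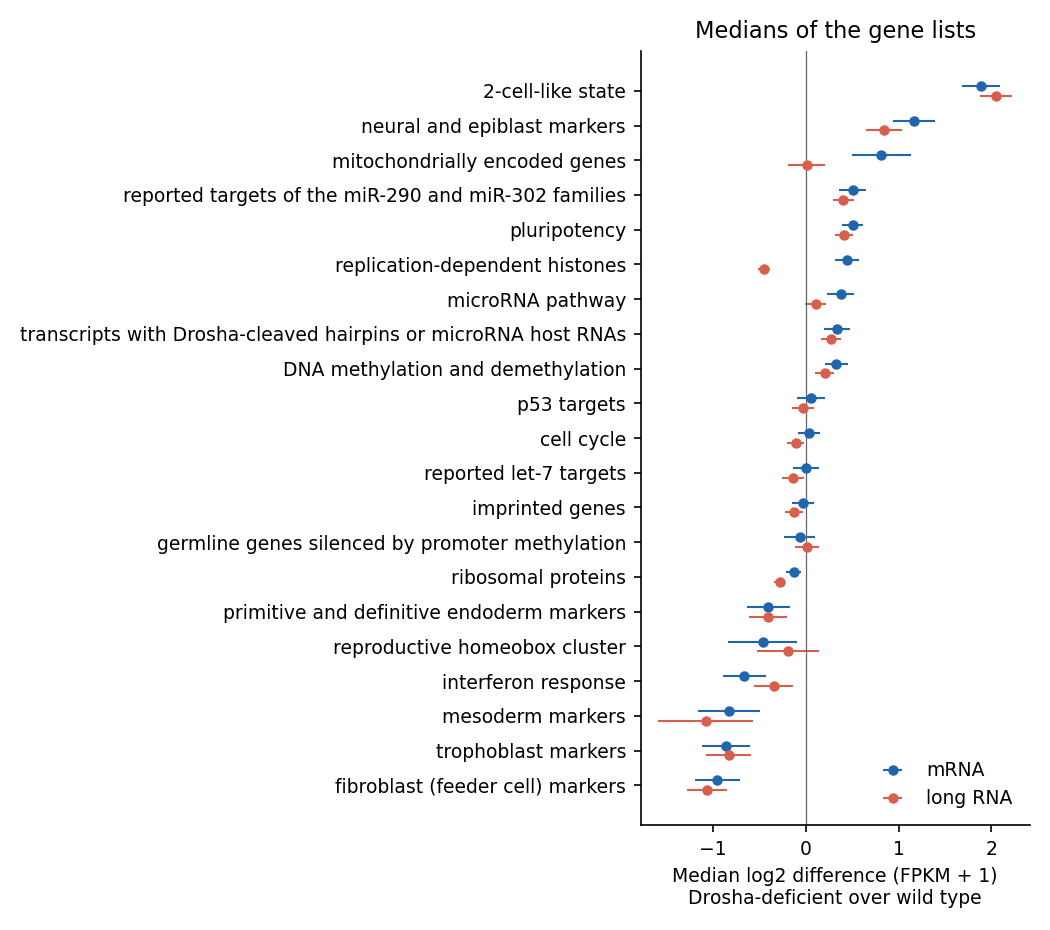
Median log2 difference, Drosha-deficient over wild type, of the genes of each list that passed the filter, in mRNA (blue) and long RNA (red), 1 library per genotype each; bars show 1 SD of the medians of matched random lists, and the line marks 0. The 2-cell-like list lies highest (1.89 in mRNA, 2.05 in long RNA) and the fibroblast list lowest in mRNA (-0.96).

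The genes that differed most in both fractions were of several kinds. Highest were 4 rows of 1 stretch of chromosome 1 (RP23-8J15.1, RP23-8J15.2, RP23-8J15.3 and RP23-8J15.4, from 24613189 to 24616197), which have no class in the RefSeq table; RP23-8J15.1 had 16.6 and 865 FPKM in mRNA and 15.0 and 299.9 FPKM in long RNA. Whether these 4 rows share reads with mitochondrial or other copies of their sequence could not be checked without a genome sequence, so their values are uncertain. The other rows of this set were the pseudogenes Gm3699, Gm9761, Gm8355 and Rpl36a-ps1, the protein-coding Gm5662, Mir136, RP24-472N17.1 and Gm26035. Gm8355 had 51.4 and 513 FPKM in mRNA. Mir136 was listed at 0 in wild-type mRNA and had 22.3 FPKM in Drosha-deficient mRNA, and went from 5128 to 16.2 FPKM in short RNA. Lowest were Igf2, Col1a2, Acta2, Col1a1, Krt19, Tagln, Fabp3 and Cisd3 among protein-coding genes, with the microRNA rows Mir379, Mir183, Mir99b and Mir5126. Krt19, a keratin of simple epithelia, had 131 and 11.4 FPKM in mRNA, Tagln, an actin-binding protein of smooth muscle, 65.0 and 5.79 FPKM, Fabp3, a fatty acid binding protein, 176 and 18.3 FPKM, and Cisd3, a mitochondrial iron-sulfur protein, 36.1 and 3.20 FPKM. Pseudogene rows and rows of microRNA length depend on few or shared reads.

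In mRNA 14752 rows were measured, of which 1275 were higher and 1170 lower (median 0.01), and in long RNA 13933, of which 872 were higher and 960 lower (median -0.04). Of the 13322 measured in both, 610 were higher in both fractions and 549 lower in both, where independent lists of these sizes would share 66.6 and 62.7. The log2 differences correlated across genes with a Pearson r of 0.772 and a Spearman rho of 0.798. The fractions may share a culture, and the labels do not say; agreement between them is not replication. With a pseudocount of 5, 232 were higher and 166 lower in both, and among protein-coding genes alone, a choice made after seeing the data, 267 and 321.

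**Figure D3:**
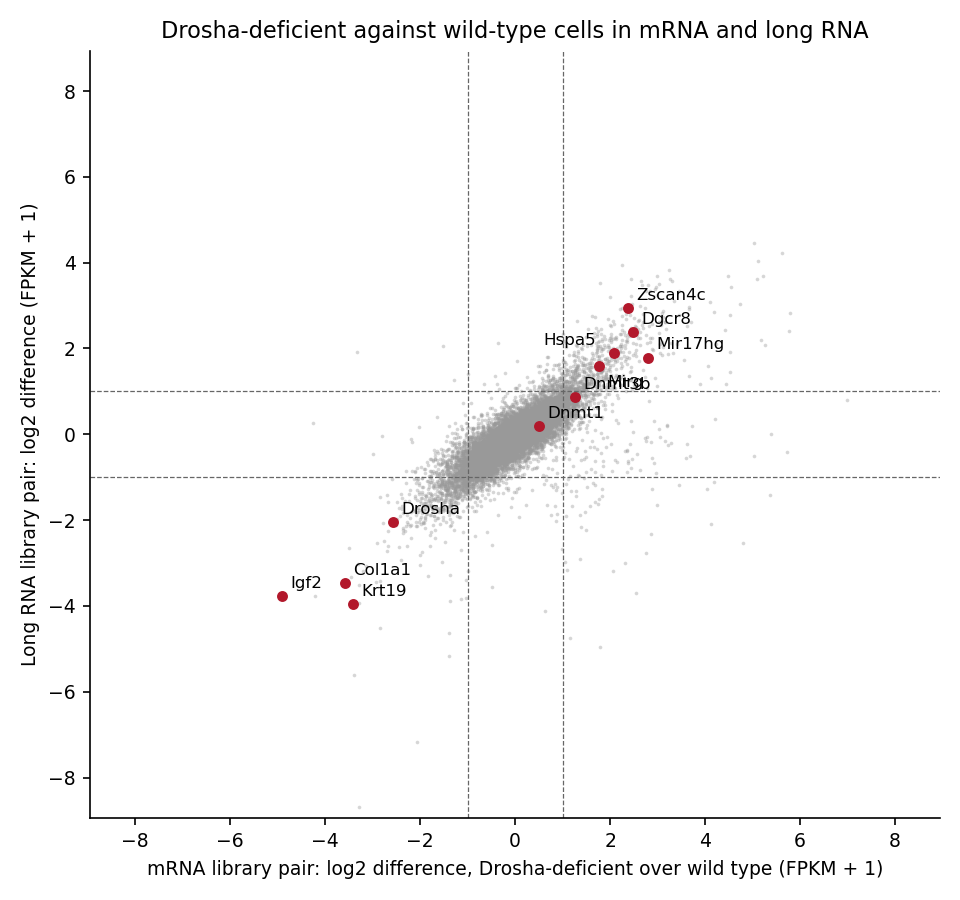
Log2 difference, Drosha-deficient over wild type, of each of 13322 genes that passed the filter in both fractions, in mRNA (horizontal) and long RNA (vertical), 1 library per genotype and fraction; dashed lines mark the 2-fold rule, and red points are example genes. Drosha, Igf2, Col1a1 and Krt19 lie low in both and Dgcr8 and Mir17hg high in both, and the Pearson r is 0.772.

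The last comparison asked where both fractions differed from each other. Small RNA genes stood out: of the 6 genes lowest in long RNA relative to mRNA, Mir434, Mir23a, Mir363 and Mir127 are microRNAs and Gm23143 and Gm22265 are small nuclear RNA genes. Mir127, in the Dlk1-Dio3 region, had 3.13 and 71.0 FPKM in mRNA but 402 and 93.2 FPKM in long RNA, and Gm23143 had 9.60 and 432.9 FPKM in mRNA but 14426 and 5447 FPKM in long RNA. The tables give Mir127, Mir136 and Mir434 the same interval (chromosome 12, 109589194 to 109600330). In the other direction were a row of chromosome 1 (69826970 to 70725132), Mir5136, Gm14039, Sfmbt2, Gm11918 and Gm25781. Sfmbt2, an imprinted gene that carries a large microRNA cluster, had 80.4 and 10.7 FPKM in mRNA and 6.25 and 6.01 FPKM in long RNA. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median of 0.44 in mRNA (percentile 100, 15 of 55 higher, 1 lower) and of -0.45 in long RNA (percentile 0, 7 of 68 higher, 18 lower); the median in mRNA was 0.20 with a pseudocount of 5 and 0.31 with a minimum of 5 FPKM. Hist1h2ap and Hist1h2aj were higher and Hist3h2ba lower in both fractions. Mitochondrially encoded genes had a median of 0.81 over 5 in mRNA (percentile 99.1) and 0.01 over 8 in long RNA (percentile 65.4), and 2 were higher in each; the named ones are the transfer RNA genes mt-Ts1 and mt-Tq. In all, the log2 differences of 436 genes lay at least 1 apart between fractions, and in 300 of these long RNA was the lower. Among protein-coding genes alone 52 were higher and 54 lower in long RNA than in mRNA, and with a pseudocount of 0.1 over all genes 310 and 459.

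By the authors' deposited table for each fraction, 19 rows were significant in mRNA (12 higher and 7 lower in Drosha-deficient cells), 19 in long RNA (12 and 7) and 85 in short RNA (6 and 79). The smallest q-value in the authors' deposited table was 0.0445 in mRNA, 0.0425 in long RNA and 0.00245 in short RNA. Of the 85 short RNA rows in the authors' deposited table, 51 are microRNA genes and 72 are listed at 0 in a genotype. Hspa5, an endoplasmic reticulum chaperone, was significant in both mRNA (152 and 647 FPKM) and long RNA (147 and 545 FPKM) in the authors' deposited table, as were RP23-8J15.2, RP23-8J15.4, Gm8355 and the muscle gene Ttn, the only 5 in common. These calls rest on 1 library per genotype.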

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

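The grouping of genes by RefSeq class and the tests of RNA without a poly(A) tail were chosen only after the results had been seen. The results of this paragraph are here because mRNA and long RNA, compared between the same genotypes, moved in opposite directions, and the difference between fractions was not tested, since each has 1 library per genotype. In mRNA 39 genes were 2-fold higher where long RNA had them 2-fold lower: 12 were microRNA genes, 6 small nuclear RNA genes, 4 small nucleolar RNA genes, 6 pseudogenes, 2 long noncoding RNA genes, and 9 had no RefSeq class. The opposite held for 4 genes, Gm14039, Mir666, Gm25781 and a row of chromosome 1 (69826970 to 70725132). RefSeq microRNA genes had a median log2 difference of 1.07 over 71 in mRNA and -1.31 over 114 in long RNA (1.08 and -1.76 over the 66 measured in both), RefSeq small nucleolar RNA genes 1.21 and -0.45, and replication-dependent histone genes 0.44 and -0.45. FPKM values of rows as short as microRNAs depend on how the authors' program corrected for transcript length, and many of these rows are low in mRNA, so their values are uncertain.

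Small nuclear RNA, small nucleolar RNA and histone genes as classes were higher in mRNA relative to long RNA: the median difference between fractions was 2.21 over 54 small nuclear RNA genes, 1.97 over 23 small nucleolar RNA genes and 0.84 over 55 histone genes, against 0.08 over 10103 other protein-coding genes. In long RNA itself the same 54 small nuclear RNA genes had a median of -0.06 (14 higher, 9 lower), while all 220 measured there had 0.44 (76 higher, 35 lower). If more RNA without a poly(A) tail had been carried into the Drosha-deficient mRNA library, structural RNAs outside these classes would be raised in mRNA relative to long RNA as well; over 19 such rows, 13 of them copies of 5S ribosomal RNA, the median difference was 2.55 (1.44 over the other 6), so carry-over may account for the difference between fractions but not for higher small nuclear RNAs in long RNA. In long RNA, which needs no poly(A) selection, Dgcr8, Mir17hg and Mirg, which have hairpins that Drosha cuts, were higher too. Their lowest log2 difference there was 1.60, which carry-over into the mRNA library does not produce. These genes were chosen after they had been seen to be higher in both fractions. Their values are therefore no independent test of carry-over, which may still add to their mRNA values. Poly(A) tails added in Drosha-deficient cells to RNAs that lack them would give the same pattern as carry-over. This difference between genotypes was not tested.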

How the results depend on the processing

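Counts over protein-coding genes alone, the 2-cell-like list without multicopy families and random lists matched on gene span were chosen only after the results had been seen. No called value changed sign under any alternative, and both correlations stayed within 0.1 of 0.772 and 0.798 under every alternative run for them. Of 215 values of named genes, 185 kept their side of the 2-fold rule under every alternative run for them, which left out summed symbols and, for 11 values, the minimum of 5 FPKM; 30 lost it with a pseudocount of 5, and 1 of these also when centred. Of 50 list medians, 22 moved by less than the spread of matched random lists throughout, and centring or keeping all rows except failed ones moved none. Which direction held more genes was not stable: in mRNA higher genes outnumbered lower ones (1275 and 1170), but not with a pseudocount of 0.1 or with protein-coding genes alone, and in long RNA lower genes outnumbered higher ones (960 and 872), but not when centred (880 and 939). In both fractions together higher genes outnumbered lower ones (610 and 549), but not with a pseudocount of 0.1 or with protein-coding genes alone. Centring moved no share of higher calls by over 10 points (47.6% to 51.6% in long RNA), and all median shifts were under 0.1. Depth limits rows of microRNA length, and low genes most in short RNA, where the counts were higher when rows the authors had not tested were let in. The cause of each change was not tested, except that a larger pseudocount shrinks, and a smaller one widens, the differences of low genes by construction, and that a subset of genes holds fewer calls. Small nucleolar RNAs gave no value under the planned filter, and no paired analysis was possible because each group has 1 library. Named genes, lists and short RNA groups were not recomputed with summed symbols.

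With a pseudocount of 5, higher and lower genes numbered 551 and 373 in mRNA, 315 and 335 in long RNA, 131 and 279 in short RNA and 232 and 166 in both mRNA and long RNA, and long RNA lay above mRNA in 32 genes. The medians in mRNA and long RNA were then 0.91 and 0.79 for the 2-cell-like list, 0.67 and 0.41 for neural and epiblast markers, -0.59 and -0.34 for fibroblast, -0.32 and -0.39 for mesoderm, -0.34 and -0.26 for trophoblast and -0.28 and -0.11 for interferon genes. In mRNA alone pluripotency moved to 0.37, endoderm to -0.13 and histones to 0.20, and in long RNA miR-290 and miR-302 targets moved to 0.20. In short RNA the medians were -4.79 for all microRNAs, -4.17 for let-7, -8.10 for Dlk1-Dio3 and -9.53 for the miR-17 to 92 family.

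With a pseudocount of 0.1, 1744 genes were higher and 1884 lower in mRNA, 1254 and 1592 in long RNA and 891 and 960 in both, and long RNA lay above mRNA in 310 and below it in 459 genes. The medians in mRNA and long RNA were 2.83 and 3.42 for the 2-cell-like list, 1.45 and 1.13 for neural and epiblast markers, -1.92 and -2.36 for fibroblast and -1.32 and -1.31 for trophoblast markers; endoderm was at -0.71 in mRNA, and mesoderm was at -2.54, interferon genes at -0.70 and miR-290 and miR-302 targets at 0.53 in long RNA. In short RNA they were -8.19 for all microRNAs, -9.71 for let-7, -11.39 for Dlk1-Dio3 and -15.17 for the miR-17 to 92 family.

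With a minimum of 5 FPKM, 960 genes were higher and 779 lower in mRNA, 542 and 647 in long RNA and 414 and 361 in both, and long RNA lay above mRNA in 49 and below it in 167. Medians in mRNA and long RNA were -2.12 and -3.47 for fibroblast, -1.66 and -1.99 for trophoblast (4 and 3 remaining genes) and -0.71 and -0.70 for endoderm markers. For the reproductive homeobox cluster only Rhox5 remained, and the values of -2.90 and -2.53 are its own. Imprinted genes moved to 0.13 and 0.0013 and germline genes to 0.17 and 0.41, so that of these uncalled medians all but that of germline genes in long RNA changed sign. In mRNA mesoderm moved to -1.23, over 2 remaining genes (0 in long RNA), and histones to 0.31; in long RNA the 2-cell-like list moved to 2.60, let-7 targets to 0.016 and miR-290 and miR-302 targets to 0.52; in short RNA all microRNAs moved to -5.86. With no minimum, mesoderm was at -0.40 and trophoblast at -0.45 in mRNA and the 2-cell-like list at 1.60 in long RNA. With all rows except failed ones, 822 genes were higher and 883 lower in short RNA. With protein-coding genes alone, 631 were higher and 692 lower in mRNA, 328 and 441 in long RNA, 193 and 229 in short RNA and 267 and 321 in both, and long RNA lay above mRNA in 52 and below it in 54. Over the few 2-cell-like genes kept as outside multicopy families, the medians were 1.40 in mRNA and 1.64 in long RNA. At a q-value of at most 0.01, 0 rows of the authors' deposited table for mRNA and 0 of that for long RNA remained. All significant rows share the same q-value, 0.0445 in the authors' deposited table for mRNA and 0.0425 in that for long RNA. A stricter threshold therefore keeps or removes them together and does not rank them. Against random lists matched on gene span, ribosomal protein genes in mRNA moved to percentile 41.6, inside the bounds. Endoderm markers moved to 1.79 in mRNA and 2.12 in long RNA, outside them. The other lists of mRNA and long RNA kept their side, and the short RNA lists were not run against such random lists.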

Other observations

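The genes, lists and tests in this part were chosen only after the results had been seen, except the marker lists for fibroblasts and for neural and epiblast cells. Of chaperones of the endoplasmic reticulum, a list put together after Hspa5 had been seen to be high, 5 of 15 measured in mRNA and 5 of 14 in long RNA were at least 2-fold higher in Drosha-deficient cells, 10 and 9 were neither, and none was lower; the median log2 differences were 0.92 and 0.84. Hspa5, the main chaperone of that compartment, went from 152 to 647 FPKM in mRNA and from 147 to 545 FPKM in long RNA. Calr, a calcium-binding chaperone, had 276 and 932 FPKM in mRNA, Pdia4, a disulfide isomerase, 42.7 and 161 FPKM, and Dnajb9, a cochaperone of Hspa5, 9.06 and 27.6 FPKM. The heat shock genes Hspa1a and Hspa1b, near-identical copies that share reads, had 0.434 and 7.06 FPKM and 1.11 and 17.1 FPKM in mRNA. Ddit3 and Trib3, stress genes of another branch, were not higher: Ddit3 had 10.3 and 3.80 FPKM and Trib3 8.82 and 4.41 FPKM.

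Several abundant genes of unrelated function were much lower in both fractions. Pgk1, a glycolytic enzyme, had 153.5 and 28.9 FPKM in mRNA, Fau, a ribosomal protein gene, 458 and 82.8 FPKM, and S100a6, a calcium-binding protein, 208 and 20.1 FPKM. Mrpl23, a mitochondrial ribosomal protein gene on chromosome 7 (142532799 to 142540747), near Igf2, had 49.9 and 5.73 FPKM, and Fos, an immediate early factor, 31.0 and 3.68 FPKM. Apoe, a lipid carrier on the endoderm list, was lower by less than these, at 306 and 129.7 FPKM. Median log2 differences per chromosome ran from -0.06 to 0.13 in mRNA and from -0.11 to 0.07 in long RNA. Over 6 groups of equal size ordered by gene span, the median went from -0.19 in the shortest to 0.31 in the longest genes in mRNA and from -0.17 to 0.09 in long RNA.

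Fibroblast, keratin and mesoderm genes had medians below 0 in the Drosha-deficient libraries, though not every gene was lower. In mRNA 8 of 17 fibroblast, 4 of 4 keratin and 4 of 9 mesoderm genes were at least 2-fold lower, and none was 2-fold higher. Krt7, Krt8, Krt18 and Krt19, keratins of simple epithelia on the trophoblast and endoderm lists, had a median log2 difference of -1.98 in mRNA and -2.29 in long RNA. Feeder fibroblasts in the wild-type libraries, which the labels do not mention, would leave these keratins in place if fibroblasts hardly make them. That premise was not checked, and the keratins were listed after some had been seen to be lower. Their values are therefore no independent test of feeders. For the fibroblast genes themselves feeders cannot be told apart, since ES cultures also express abundant fibroblast transcripts. Of these, Sparc (222 and 219 FPKM in mRNA), Fn1 (209 and 179 FPKM) and Vim (153.9 and 90.5 FPKM) had a median of -0.32 over both fractions. Neural and epiblast markers were higher, with a median of 1.17 in mRNA. Their list shares Otx2 with the pluripotency list and Dnmt3b with the methylation list, so it does not measure differentiated cells alone. The list therefore cannot decide whether the Drosha-deficient culture held fewer differentiated cells of every kind. A trend with gene length leaves a difference of -0.95 between the median of the fibroblast list, of which 17 of 24 genes were measured in mRNA, and those of random lists of like span, in the fraction where they lie closest. A culture with fewer cells of mesodermal, epithelial or fibroblast kind, or lower expression of these genes within each ES cell, stays open as a biological explanation and was not tested.

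In short RNA many genes not named as microRNAs were lower by a log2 difference of at least 3 in size, among them Clcn5 (10334 and 12.2 FPKM), Vmp1 (12979 and 30.1 FPKM), Mcm7 (6455 and 24.2 FPKM) and Huwe1 (2477 and 10.9 FPKM). Of the 62 such rows not named for a microRNA, 67.7% hold an annotated microRNA gene, against 6.01% of 1731 rows that differed by less than 2-fold and 7.80% of those at like spans, so reads of microRNAs inside these genes may account for most of them. Among the others are Rpl5 (68307 and 1118 FPKM) and Tmem38b (5970 and 239.8 FPKM), in which the RefSeq table lists no microRNA, and their values stay unexplained. Short RNA values of such genes are not levels of their mRNA.

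A hypothesis from the series title is that imprinted genes follow a loss of methylation at their control regions. Genes expected higher on such a loss had a median log2 difference of 0.27 in mRNA (percentile 91.9, 3 of 17 higher, none lower) and 0.25 in long RNA (percentile 98.4, 2 of 19 higher, 2 lower); genes expected lower had medians of -0.91 (percentile 0.02, 5 of 11 lower) and -0.67 (percentile 0.36, 4 of 10 lower), with none higher. On chromosome 7 Cdkn1c (15.7 and 5.61 FPKM in mRNA), Phlda2 (71.6 and 30.5 FPKM), Slc22a18 (3.78 and 0.382 FPKM) and Osbpl5 (2.64 and 0.945 FPKM), which are repressed when that control region is unmethylated, were all at lower levels. Of the genes expected higher, Kcnq1ot1, the RNA of that control region, had 2.997 and 6.396 FPKM in long RNA. In mRNA Mest had 60.0 and 134.6 FPKM, Ndn 11.98 and 22.6 FPKM and H19 45.1 and 56.9 FPKM. Ndn and H19 were not called higher, and H19 in long RNA had 26.4 and 26.5 FPKM. Peg10 and Sgce were lower in long RNA. The mRNA row of Peg10 (148 and 68.3 FPKM) had failed status and was left out of the mRNA count. The genes expected lower include growth and placental genes that lie with the other lower markers, and with the higher set inside the range of random lists in mRNA the hypothesis could be neither supported nor excluded; the methylation samples were not analysed here.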
